A study of Mus musculus with 14 samples.

How the data were processed

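RNA from small intestine biopsies of mice was measured in 3 groups: granulomas of mice infected with H. poly, granuloma-free tissue of infected mice, and tissue of uninfected mice. Per the labels' protocols, RNA was extracted with a Trizol-based method and polyA RNA libraries were made with Illumina kits and sequenced on a HiSeq instrument. Whether the kits mark strand is not given in the sources used here. The authors deposited whole-number read counts per gene for 14 libraries, not normalized. The submitters' processing notes name mm10, STAR, featureCounts, DESeq2 and deepTools, without versions or settings. The strand setting of the counting is not given in the sources used here. The labels do not say whether samples of a group came from separate animals, so p-values measure the spread between samples, part of which may be technical. Nor do they say whether granuloma and granuloma-free samples came from the same infected mice.

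The table has 54532 rows with Ensembl identifiers, of which 54495 matched a stable identifier of the GENCODE annotation of mm10 and 37 did not. A total of 43177 rows hold no read. The libraries hold 245201 to 617077 counts, which is shallow, and 1629 rows passed the filter for testing. Gene symbols, coordinates (mm10, counted from 1), exons, coding sequence and UTRs come from that annotation, and gene biotypes as well.

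Before any test, the rows were compared with the annotation of the other strand. Rows with an exonic base shared with a gene on the opposite strand made up 16.7% of rows and held 97.1% of all reads, 95.8% to 97.7% per library. Of the 100 rows with the most reads, 99 had such an overlap. Abundant messengers held few or no reads in their own rows: Eef1a1 and Rpl3 held 0 reads, Actb 48 and Gapdh 184, summed over all libraries. The 79 ribosomal protein rows held 0.0580% of the reads, and 44 of them held 0. On the mitochondrial genome, mt-Nd6, the protein-coding gene of the minus strand, held 186459 reads and mt-Co1 on the plus strand 150. Minus-strand rows held 96.9% of the mitochondrial reads. Each row is therefore reported with the gene or genes that share at least 20 exonic bases with it on the opposite strand, called its opposite gene. Of the tested rows, 1070 had 1 opposite gene, 283 had more than 1, so that reads could come from any of them, and 276 had none. If the reads come from the opposite gene, only the shared segment is counted, so levels cannot be compared between genes and the sense and antisense sources of a row cannot be separated from these counts.

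Tests ran in edgeR 4.0.16 with limma 3.58.1 under R 4.3.3. Rows were filtered with filterByExpr by group (minimum count 10), scaled with TMM factors, and fitted with glmQLFit and glmQLFTest, robust, with all 14 libraries in one group design and no covariate. Adjusted p-values are Benjamini-Hochberg values over the 1629 rows, with a threshold of 0.05. The common biological coefficient of variation was 0.425. CPM values use the TMM-scaled totals, and log2 CPM a prior count of 2. Fold changes are log2 with their standard error (SE). Group values are mean ± SD over libraries. Pairs of replicates in a group differed by far more than sampling noise (chi-square per degree of freedom 9.73 to 56.0), so no library was counted as a copy of another.

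The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names a fixed panel of 18 genes and, per comparison, the 5 highest and 5 lowest called rows with a mean count of at least 50 in a group and no overlap between the libraries of the groups, leaving out predicted genes. After the data were seen, the rule was extended by the 8 highest and 8 lowest such rows with exactly 1 protein-coding opposite gene. It was also extended by all called rows with an opposite gene in a fixed list, whatever their mean count. The planned list test needed at least 4 tested rows named for members of a list. None of the 41 lists reached that number (at most 3), so neither it nor the planned list scores gave a value. Instead, lists were matched to single opposite genes, which left 1 list with at least 4 rows, the tuft cell list. That match, and a comparison with 7 gene families picked by symbol, were chosen after seeing the data. Set tests used limma camera with a preset correlation of 0.01, adjusted over 24 tests, and also an estimated correlation and fry. Single scores were compared with a two-sided exact permutation test.

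On simulated counts with 200 rows changed, drawn from the means, library sizes and spread of these data, the test recovered 28% of the 2-fold and 80% of the 4-fold changes for granuloma against infected non-granuloma. For granuloma against uninfected it recovered 29% and 71%, and for infected non-granuloma against uninfected 15% and 82%. False calls were 5.26%, 3.85% and 3% of the calls. Rows were drawn independently in these simulations, so trends carried by whole libraries are not in these rates. Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma-voom with quality weights, a test against a fold of 1.5, only the groups compared, a block on the replicate number, and leaving out each library in turn. Added after seeing the data were a covariate for a row opposite Malat1, the removal of 5 libraries with over 100 reads opposite pancreatic protease genes, and a count restricted to rows with an opposite gene. Figures were drawn with matplotlib 3.10.9.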

Results

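PolyA RNA of mouse small intestine biopsies was sequenced in 3 groups. They were granulomas (n = 5) from mice infected with H. poly (a helminth of the gut), tissue without granuloma from infected mice (n = 4), and tissue of uninfected mice (n = 5). Total counts per library were 245201 to 417223 for granuloma, 462604 to 617077 for infected non-granuloma and 256118 to 468180 for uninfected tissue. The reads lay almost wholly on rows that overlap a gene on the other strand. The Gm10680 row (chromosome 9, 46242621 to 46243529, minus strand) alone held 14.3% of all reads. It shares 632 exonic bases, 520 of them coding, with Apoa4, an apolipoprotein of absorptive enterocytes. The Ccdc152 row held 5.59% and shares 439 bases with the 3' end of Selenop, a selenium transport protein, in its UTR. Each row below is given with its opposite gene.

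The libraries also differed in ways that the groups do not explain. The Gm37376 row (chromosome 19, 5801941 to 5802393, plus strand), which lies inside the nuclear noncoding RNA Malat1 on the other strand, ranged from 2471 to 15594 CPM in granuloma, 728 to 9949 in infected non-granuloma and 2552 to 24414 in uninfected libraries. The Casp9 row, opposite the pancreatic proteases Cela2a and Ctrc, exceeded 100 reads in 5 libraries, granuloma 2, 4 and 5 and uninfected 3 and 4. It reached 18940 CPM in granuloma 4, and stayed between 15.1 and 93.1 CPM in the infected non-granuloma libraries.

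The comparison of granuloma with uninfected tissue asked what differs in the lesion. The Duoxa1 row, opposite Duoxa2, the maturation factor of the hydrogen peroxide-producing oxidase Duox2, stood at 27204 ± 17818 CPM (SD, n = 5) in granuloma and 272 ± 81.6 (n = 5) in uninfected tissue. That is a log2 fold change of 6.65 ± 0.52 (SE, edgeR adjusted p = 1.3e-06). The Gsdmcl2 row, a gasdermin C-like pseudogene with close relatives and no opposite gene, rose from 5.37 ± 6.82 to 774 ± 307 CPM. The Slc13a2os row, opposite the citrate transporter Slc13a2, fell from 233 ± 74.9 to 17.5 ± 10.7 CPM (log2 fold change -3.72 ± 0.44). Opposite Dpp4, a brush-border peptidase, the Gm13561 row fell from 108 ± 39.5 to 19.1 ± 10.1 CPM.

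**Figure D1:**
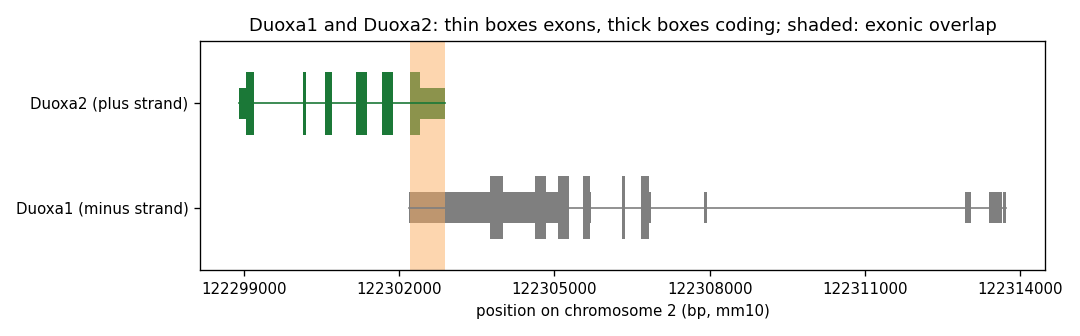
Exons of Duoxa1 (minus strand) and Duoxa2 (plus strand) by position on chromosome 2 (base pairs, mm10), with thick boxes for coding sequence and thin boxes for other exonic sequence. The shaded stretch from 122302204 to 122302885 is the 682 exonic bases that both genes share, 191 of them coding and 491 in the UTR of Duoxa2.

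Among the other rows that rose in granuloma against uninfected tissue, Copg2 lies opposite the imprinted gene Mest. Its log2 fold change was 3.90 ± 0.43, from 12.4 ± 8.65 to 184 ± 52.2 CPM, over 912 bases in the UTR of Mest. Gm15856 lies opposite the tubulin gene Tuba8 and rose by 3.64 on the log2 scale, Gm26892 opposite the transporter Mfsd4a by 2.50, and Gm26716 opposite the proteoglycan Sdc3 by 1.99. The Trpt1 row, opposite the blood cell integrin regulator Fermt3, rose by 2.02, and the Polr2b row, opposite the secreted Igfbp7, by 1.74. Crls1 (3.30) and Ccdc184 (2.47) rose without an opposite gene. Rows with several opposite genes also rose. Gm10602, opposite Inppl1 and the folate receptor Folr2, was at 201 ± 68.9 CPM against 3.72 ± 6.94. Pcsk7 (opposite Rnf214 and Tagln) rose by 2.41, and Gm47079 (opposite Icam4, Icam1 and Icam5) by 1.46. The Gm20481 row, opposite the heat shock gene Hspa1a, rose by 2.66 and the Gm48529 row, opposite the smooth muscle gene Tagln, by 1.93.

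Rows that fell in granuloma against uninfected tissue included Dlec1, opposite the peroxisomal thiolase Acaa1b (log2 fold change -2.83 ± 0.37, 124 ± 64.0 against 890 ± 289 CPM). Luc7l3 fell without an opposite gene (-2.74). Gpr89, opposite Pdzk1 and Gja5, changed by -2.38, and Ncaph2, opposite Sco2 and Tymp, by -2.28. Further falls were seen opposite Ano6 (Gm49172, -1.92), the nuclease Dnase1 (Trap1, -1.72), Tesk2 (Toe1, -1.63), Tmem243 (Dmtf1, -1.50), the sugar phosphate mutase Pgm3 (Dop1a, -1.36) and the choline phosphotransferase Chpt1 (Sycp3, -1.34). The Tomm40l row, opposite the nuclear receptor Nr1i3, had a log2 fold change of -1.21, the Usp37 row, opposite Cnot9 and Vil1, of -0.63, and the Gm10680 row, opposite Apoa4, of -1.04. Single libraries decided several of these calls. The call of Gm10680 ended without granuloma 2, 3, 4 or 5 or uninfected 1, 2, 3 or 5 (log2 fold change -1.06 to -0.90 in those fits), and that of Usp37 without granuloma 1, 4 or 5 or uninfected 1, 2 or 3 (-0.66 to -0.54). The call of Gm20481 ended without granuloma 1, 3 or 5 or uninfected 1, 3 or 5 (2.37 to 2.87), and that of Gm48529 without granuloma 2 or uninfected 2 (1.20 to 1.81). In all, 201 of 1629 rows passed the threshold in edgeR, 105 higher and 96 lower in granuloma. Scaling by library totals shifted all log2 values by a median of 0.36 and gave 253 higher and 47 lower rows. Against a fold of 1.5, 76 rows passed. Without the 5 libraries with over 100 reads in the Casp9 row, a setting chosen after seeing the data, 116 rows passed.

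**Figure D2:**
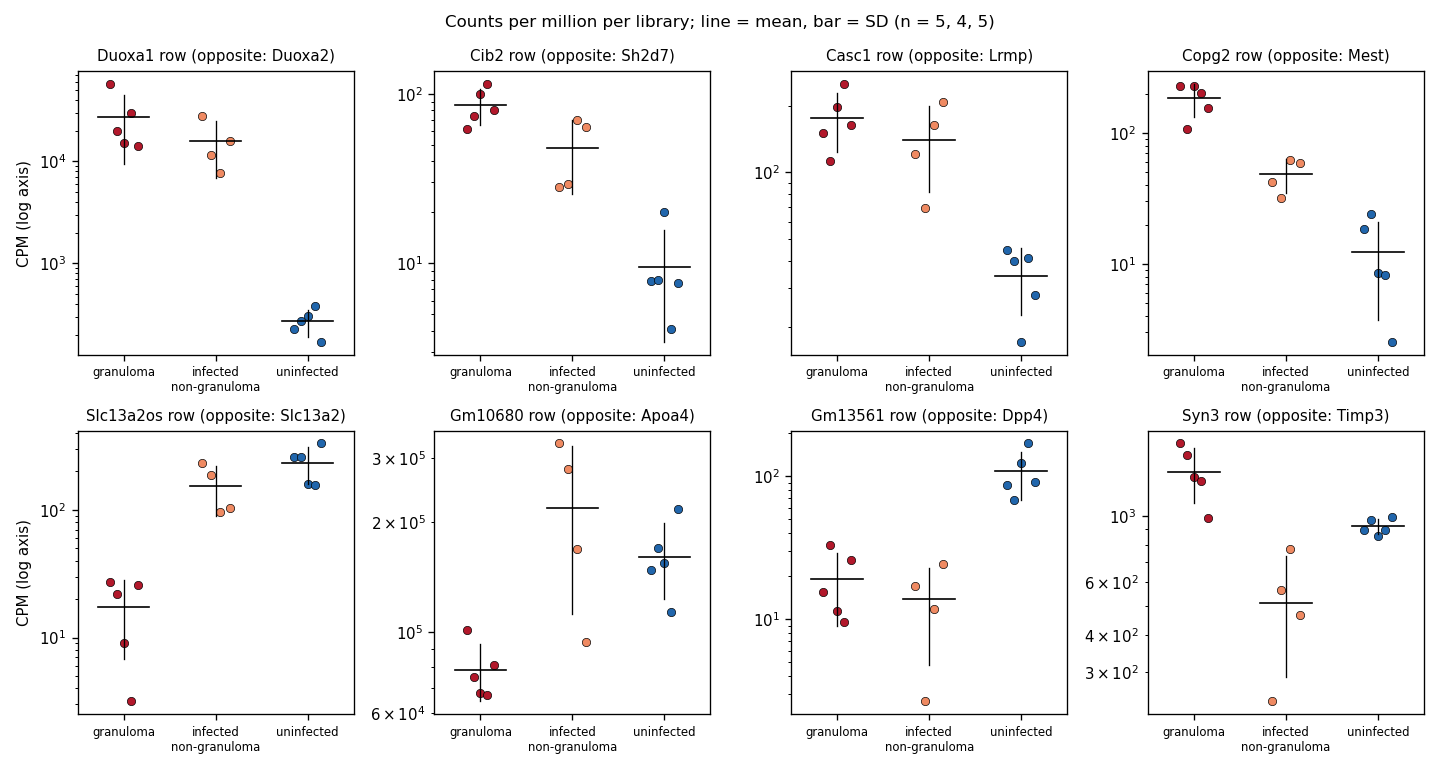
CPM (log axis) of 8 rows in each library of the 3 groups, with the opposite gene in each title, means as lines and SDs as bars (n = 5, 4 and 5). All libraries of infected mice lie above the uninfected ones opposite Duoxa2, Sh2d7, Lrmp and Mest and below them opposite Dpp4.

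Infected tissue without granuloma was compared with uninfected tissue to ask what infection changes outside the lesion. The Duoxa1 row, opposite Duoxa2, was again far higher in infected tissue, at 15782 ± 8844 CPM (SD, n = 4) against 272 ± 81.6 (n = 5), a log2 fold change of 5.86 ± 0.51 (SE, edgeR adjusted p = 6.0e-06). Gsdmcl2 rose to 217 ± 178 CPM from 5.37 ± 6.82. The Gm13561 row, opposite Dpp4, fell to 13.8 ± 9.04 from 108 ± 39.5 CPM. The Fuom row, opposite Prap1, a secreted protein of the small intestine, fell to 14281 ± 8813 from 69298 ± 36541 CPM (log2 fold change -2.28 ± 0.52, over 169 coding bases of Prap1).

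Fam84a (3.38), Tram1 (2.81) and Mtcl1 (2.77) rose in infected non-granuloma tissue without an opposite gene. Rows with 1 opposite coding gene that rose were Casc1 opposite Lrmp (2.05), Cib2 opposite Sh2d7 (2.27), Ccdc73 opposite Eif3m (1.81), Rec114 opposite Nptn (1.63) and Pkd1 opposite the growth regulator Tsc2 (1.52). Vil1 opposite Usp37 (1.51), Rac1 opposite Daglb (1.41) and Ccdc78 opposite Fam173a (1.38) rose as well. Pcsk7 (opposite Rnf214 and Tagln) rose by 1.83 and Gm10602 (opposite Inppl1 and Folr2) by 2.39. Rows that fell lay opposite the ATPase Vcp (1700022I11Rik, -3.02), the cyclin Ccnd2 (Gm43126, -2.90), Ntan1 (Pdxdc1, -2.88), Atp8a1 (Shisa3, -2.78) and Snx16 (Chmp4c, -2.52). Others were opposite the interferon response factor Irf1 (Gm17334, -2.52), Nrbp1 (Gm9970, -2.35), Rmnd1 (Gm16153, -2.30) and Neurog3, the transcription factor of enteroendocrine progenitors (Fam241b, -1.80). The Fam241b row held few reads, at 8.53 ± 2.65 CPM (n = 4) in infected non-granuloma against 30.7 ± 17.9 (n = 5) in uninfected tissue. Arhgap27, opposite Arhgap27os1 and Arhgap27os2, changed by -2.48. Removing any 1 infected non-granuloma library ended the calls opposite Neurog3 (log2 fold change -1.93 to -1.48 in the fits that ended it) and Irf1 (-2.78 to -2.07) and that of Gm10602 (2.02 to 2.61). They also ended without uninfected 1 or 4, those of Neurog3 and Gm10602 without uninfected 3 or granuloma 1 or 5, those of Irf1 and Gm10602 without uninfected 5, that of Neurog3 without granuloma 2, and that of Gm10602 without granuloma 3. The call of Ccdc78 ended without infected non-granuloma 1 or 2 or uninfected 1, 3 or 4 (as low as 0.96), and that of Ccdc73 without infected non-granuloma 1 or uninfected 1 or 4 (1.43 to 1.65). Without infected non-granuloma 1 or 2 those of Rac1 (1.21 to 1.26) and Gm16153 (-2.31 to -1.95, also without uninfected 4) ended, and without infected non-granuloma 1 that of Gm9970 (-2.33).

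Between infected non-granuloma and uninfected tissue 291 rows passed in edgeR, 155 higher and 136 lower. Of the 155 higher rows, 65 had no opposite gene, against 276 of 1629 rows tested (Fisher's exact test, p = 5.5e-15, across rows, which are not independent). Among the 136 lower rows 18 had none (Fisher's exact test, p = 0.282). In granuloma against uninfected tissue it was 24 of 105 higher rows (Fisher's exact test, p = 0.106) and 16 of 96 lower rows. Between granuloma and infected non-granuloma tissue Fisher's exact test gave p = 0.457 for higher and p = 0.834 for lower rows. The Gm37376 row inside Malat1 averaged 4660 ± 3967 CPM (n = 4) in infected non-granuloma and 13359 ± 10339 (n = 5) in uninfected libraries. With its log2 CPM as a covariate, chosen after seeing the data, 111 rows passed, 108 of them among the 291. The count also depended on single libraries: it was 90, 142 and 132 without infected non-granuloma 1, 2 and 3, and 151, 185 and 127 without uninfected 1, 3 and 4. It was 82 against a fold of 1.5, 190 with library totals, 152 with a stricter filter, 154 without the 5 libraries with over 100 reads in the Casp9 row and 146 over rows with an opposite gene.

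Granuloma was compared with non-granuloma tissue of infected mice to separate the lesion from the rest of the infected gut. The Gm48529 row, opposite Tagln, a smooth muscle actin-binding protein, was higher in granuloma at 635 ± 597 CPM (SD, n = 5) against 82.1 ± 42.9 (n = 4), a log2 fold change of 2.92 ± 0.58 (SE, edgeR adjusted p = 0.0108). The Gm26735 row, opposite the transcription factor Sox4, stood at 2677 ± 1220 against 597 ± 220 CPM (2.16 ± 0.43, over 2616 bases in the UTR of Sox4). The Syn3 row, opposite the metalloproteinase inhibitor Timp3, stood at 1396 ± 292 against 510 ± 221 CPM. The Slc13a2os row, opposite Slc13a2, was lower in granuloma, at 17.5 ± 10.7 against 155 ± 65.3 CPM (-3.11 ± 0.45), and the Gm10680 row, opposite Apoa4, stood at 78536 ± 14000 against 218394 ± 106637 CPM.

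Other rows higher in granuloma than in infected non-granuloma tissue were Copg2 opposite Mest (log2 fold change 1.89), Gm15856 opposite Tuba8 (1.71), Gm45507 opposite the mitophagy receptor Bnip3 (1.65) and Irf5 opposite the nuclear import factor Tnpo3 (1.62). Gm26716 opposite Sdc3 (1.58), Gm26883 opposite Tshz2 (1.54), Unc13a opposite the collagen galactosyltransferase Colgalt1 (1.29), Tbc1d17 opposite Il4i1 and Akt1s1 (1.53) and Gm10602 opposite Inppl1 and Folr2 (3.45) rose too. Lower rows were Por without an opposite gene (-2.95), Phldb1 opposite the noncoding Gm47239 (-2.91), Trap1 opposite Dnase1 (-2.01), Dlec1 opposite Acaa1b (-1.74) and Pcca opposite Ggact (-1.36). Ccdc152 opposite Selenop (-1.24), Recql5 opposite Sap30bp (-1.22), Zyx opposite Epha1 (-1.18), Wdr54 opposite Rtkn (-1.13), Usp37 opposite Cnot9 and Vil1 (-1.02) and Tomm40l opposite Nr1i3 (-0.95) fell as well. The rows opposite Timp3 and Bnip3 were lower in infected non-granuloma than in uninfected tissue (log2 fold changes -0.85 ± 0.27 and -0.95 ± 0.28) and did not pass between granuloma and uninfected tissue (0.60 ± 0.25 and 0.70 ± 0.26). The call opposite Timp3 against uninfected tissue ended without granuloma 2 or 3, infected non-granuloma 1, 2 or 4 or any 1 uninfected library (-0.90 to -0.62), and that opposite Bnip3 without infected non-granuloma 1, 3 or 4 or uninfected 3, 4 or 5 (-1.03 to -0.72). The Gm13561 row, opposite Dpp4, had a log2 fold change of 0.43 ± 0.51 and did not pass. The Duoxa1 row, opposite Duoxa2, had 0.79 ± 0.43 and did not pass either.

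In edgeR 69 rows passed between granuloma and infected non-granuloma tissue, 29 higher and 40 lower. Of the 25 named above, 14 did not pass without infected non-granuloma 1 (higher rows at 1.21 to 2.72, lower rows at -2.63 to -0.93). They were Copg2, Irf5, Tbc1d17, Unc13a, Por, Dlec1, Gm48529, Gm26735, Gm15856, Gm26883, Ccdc152, Recql5, Zyx and Gm10680. Without infected non-granuloma 2, 12 did not pass (1.18 to 2.78 and -2.82 to -0.91), the same rows less Gm26735, Recql5 and Zyx and with Tomm40l. Further calls ended without granuloma 1 (Irf5, Unc13a, Ccdc152, Zyx), 3 (Irf5, Tbc1d17, Ccdc152, Recql5, Tomm40l), 4 (Unc13a) and 5 (Tbc1d17, Unc13a, Ccdc152, Recql5), and without infected non-granuloma 3 (Gm15856, Recql5) and 4 (Irf5, Tbc1d17, Unc13a). In these fits Irf5 stood at 1.37 to 1.65, Tbc1d17 at 1.27 to 1.73, Unc13a at 1.18 to 1.28, Ccdc152 at -1.21 to -0.98, Recql5 at -1.17 to -1.08, Zyx at -1.09 to -0.93, Tomm40l at -0.91 to -0.88 and Gm15856 at 1.63 to 1.66. Library totals shifted the log2 values by a median of 0.28 and gave 53 higher and 10 lower rows. The count was 37 and 40 without granuloma 1 and 3, and 20 and 27 without infected non-granuloma 1 and 2. With a block on the replicate number, which is not known to pair samples, it was 0. It was 12 against a fold of 1.5, 158 with DESeq2, 109 with limma-voom and with no filter, and 126 without the 5 libraries with over 100 reads in the Casp9 row, of which 38 were among the 69.

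Rows called in both comparisons with uninfected tissue numbered 87, 51 higher and 36 lower, Duoxa1, Gsdmcl2, Cib2, Casc1 and Copg2 among the higher and Gm13561 among the lower. No row was called in opposite directions by edgeR. With library totals 105 rows were shared, 85 higher and 20 lower. Lists of these sizes would share 9.99 higher and 8.01 lower rows if independent. In 50 simulations of unchanged groups against the same controls the shared calls were 0, but each comparison there had at most 1 call, so that count could hardly differ from 0 and is no measure for the overlap. The log2 fold changes correlated across rows at r = 0.67, against 0.49 in those simulations, with a covariance of 0.71 against 0.12, a difference of 0.59. Rows were drawn independently there, so trends carried by whole control libraries are not in the simulated values. With the 5 uninfected libraries divided between the comparisons, r was 0.10 to 0.60 and the covariance 0.15 to 0.70 over 20 divisions. Rows are not independent replicates. With the 5 uninfected libraries divided into sets of 3 and 2, one set per comparison, the shared calls numbered 1 to 26 over 20 divisions (median 11.5), and 3 divisions gave 1 to 3 rows called in opposite directions. Single libraries mattered: 51 and 54 rows were shared without infected non-granuloma 1 and 3, and 48 and 52 without uninfected 1 and 4. The number was 35 without the 5 libraries with over 100 reads in the Casp9 row and 50 over rows with an opposite gene.

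Tuft cells, chemosensory epithelial cells that respond to gut parasites, were the subject of 1 fixed list, and 6 tested rows had a member as their single opposite gene. They were Actr8 (opposite Il17rb), Chtf18 (Gng13), Cib2 (Sh2d7), Casc1 (Lrmp), Gm43621 (Ptgs1) and Gm19719 (Alox5ap). Il17rb is also on the fixed list for T helper 2 and type 2 innate lymphoid cells. Uninfected levels of Gm19719, Chtf18, Cib2 and Gm43621 were low, at 7.40, 8.11, 9.54 and 11.8 CPM, so they rest on few reads. Matching the list in this way was chosen after seeing the data. Against uninfected tissue 4 of the 6 rose in granuloma, 5 adjusted over the list alone, with a median log2 fold change of 1.91 (camera adjusted p = 2.0e-04, adjusted p = 0.0486 with an estimated correlation, fry adjusted p = 3.5e-05). The row opposite Sh2d7 led with 3.10 ± 0.43 (86.0 ± 20.9 against 9.54 ± 6.10 CPM), followed by those opposite Lrmp with 2.36 ± 0.35, Gng13 with 1.84 ± 0.48 and Il17rb with 1.79 ± 0.48. The call opposite Il17rb ended without granuloma 3 or uninfected 1 or 5 (1.39 to 1.81) and that opposite Gng13 without uninfected 1 or 5 (1.71 to 1.72). Of the 6 rows, 2 passed without uninfected 1, 3 without granuloma 3, and 3 without uninfected 5, where another row gained a call. In infected non-granuloma against uninfected tissue 2 of the 6 rose, 2 adjusted over the list alone, those opposite Sh2d7 and Lrmp (median 1.30, camera adjusted p = 0.0225, adjusted p = 0.206 with an estimated correlation, fry adjusted p = 0.00196). Between granuloma and infected non-granuloma none of the 6 passed in edgeR or DESeq2, 1 had an unadjusted p under 0.05 in each tool, and the median was 0.71 (camera adjusted p = 0.312, fry adjusted p = 0.0417). Without the 5 libraries with over 100 reads in the Casp9 row 3, 2 and 1 of the rows passed in these comparisons, and with the Malat1 covariate 5, 3 and 0.

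**Figure D3:**
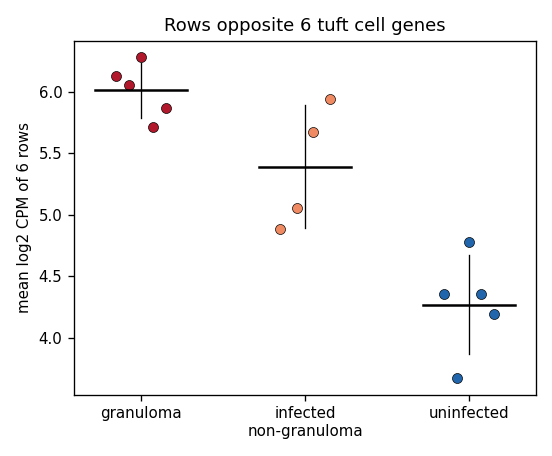
Mean log2 CPM of the 6 rows opposite tuft cell genes in each library, with the mean (line) and SD (bar) of each group. Every granuloma and infected non-granuloma library lies above the highest uninfected library at 4.78.

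The mean log2 CPM of the 6 rows was 6.01 ± 0.22 (n = 5) in granuloma, 5.39 ± 0.50 (n = 4) in infected non-granuloma and 4.27 ± 0.40 (n = 5) in uninfected tissue. By exact two-sided permutation tests the differences from uninfected tissue had p = 0.00794, the smallest that these group sizes allow, for granuloma and p = 0.0159 for infected non-granuloma tissue. The difference of 0.62 between granuloma and infected non-granuloma tissue had an exact permutation p = 0.0476. It did not pass without any 1 of the granuloma libraries (differences of 0.55 to 0.69) or without infected non-granuloma 1, 2 or 3 (0.45, 0.51 and 0.71). With library totals the differences were 2.03, 1.16 and 0.87.

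The remaining lists had few rows. From the absorptive enterocyte list, 2 genes were the single opposite gene of a tested row. The row opposite Dpp4 fell in both groups of infected mice, and the main row opposite Apoa4 was lower in granuloma than in each other group. A second row opposite Apoa4, Gm47528, had log2 fold changes of -0.30 ± 0.78 between granuloma and uninfected tissue, 1.24 ± 0.88 between granuloma and infected non-granuloma tissue, a sign other than that of the main row, and -1.55 ± 0.89 between infected non-granuloma and uninfected tissue, and did not pass in any of them. For the interferon gamma list the row opposite Irf1 fell in infected non-granuloma tissue and that opposite Cxcl10 (Art3, -0.23 ± 0.41) did not pass. Between granuloma and infected non-granuloma tissue these rows stood at 2.29 ± 0.73 and 0.49 ± 0.41, and between granuloma and uninfected tissue at -0.23 ± 0.63 and 0.26 ± 0.39, without passing over all rows. The row opposite Irf1 (Gm17334), at 2.29, had an adjusted p of 0.0845 over all rows and 0.0135 over the list alone. Opposite the cell cycle genes Cdc20 and Mcm7, the rows Elovl1 (0.68 ± 0.28) and Cops6 (0.15 ± 0.29) did not pass between granuloma and uninfected tissue. In infected non-granuloma against uninfected tissue they stood at 0.60 ± 0.29 and 0.81 ± 0.30 (adjusted p = 0.0721 for Cops6 over all rows and 0.0328 over the list alone), and between granuloma and infected non-granuloma tissue at 0.08 ± 0.29 and -0.66 ± 0.30, without passing over all rows. None of the 18 panel genes could be tested by its own row. The cytokine Il4 held 18 reads over all libraries, Apoa4 30, and 16 others, among them Il5, Il13, Il25, Il33, Retnla, Arg1, Chil3, Mcpt1, Epx, Dclk1, Retnlb, Lgr5, Ly6a, Ifng, Reg3g and Col1a1, held at most 2 each. At this strand and depth differences were not detectable in their own rows. The main row opposite Apoa4, given above, did differ.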

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

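Of the tests in this part, those of the splits were planned, and the weighing of the strand, of the Malat1 trend and of the rows without an opposite gene was chosen after the results were seen. For each comparison, 100 splits of its libraries into groups of the same sizes, the real one included, were fitted, and 1 of them, the real one, called as many rows. Between granuloma and infected non-granuloma tissue the real split called 69 rows and the highest other 54, with granuloma 4 and infected non-granuloma 4 exchanged. Between granuloma and uninfected tissue the values were 201 and 53, and between infected non-granuloma and uninfected tissue 291 and 3. A chance division of the libraries can thus be excluded as the source of these 3 counts at the level of 1 in 100. For the 87 shared calls, 1 of 100 regroupings of all libraries, the real one, gave as many, and the highest other gave 4. The other splits of each comparison called a median of 0 rows, which leaves little to share, so this excludes a chance division only, and does not show how much of the 87 the shared uninfected libraries add (median 11.5 with these divided).

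The reads lie on the strand opposite to the genes that name the rows. A candidate explanation is that the libraries keep strand and were counted with the opposite setting, so that each row holds transcripts of the gene across from it. In that case minus-strand rows should hold most mitochondrial reads, since most mitochondrial messengers come from the plus strand, and they held 96.9%. Antisense transcripts counted correctly are argued against by the ribosomal protein rows, which held 0.0580% of the reads, and a kit that does not keep strand by the lowest share of mitochondrial reads on minus-strand rows in a library, 93.0%, not near an even division. No other biological explanation was tested, and the settings of the counting stay unknown.

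The rows called between infected non-granuloma and uninfected tissue partly follow the row inside Malat1. Within groups, the median r with that row was 0.52 for the 136 lower rows and -0.47 for the 155 higher rows. For rows not called it was 0.01. A trend between libraries within groups, which might be RNA quality or nuclear RNA, is thus a candidate part of the cause. The r was not computed for each group alone, so a trend in every group is not shown. Whether the trend is the whole cause cannot be told from these counts. With the covariate the median log2 change of the 291 rows, in the direction of the call, was 1.38 with a median SE of 0.44, against 1.81 and 0.45 before. The rows and their directions were picked by calls in the same data, so this median was likely to stay above its SE. In the 183 rows that lost their call the median fell from 1.62 (SE 0.50) to 1.25 (SE 0.47), a larger drop than that of the SE, and whether the covariate took up group differences there was not tested. The infection itself, which the design names, stays open as untested.

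The 65 higher rows without an opposite gene in infected non-granuloma tissue, among them Gsdmcl2, Fam84a, Tram1 and Mtcl1, held 0.832% ± 0.0609 (SD, n = 4) of the reads there, 0.680% ± 0.303 (n = 5) in granuloma and 0.208% ± 0.0619 (n = 5) in uninfected libraries. Transcripts of the parasite as the sole source are argued against, since 65 of the 65 rows held over 3 reads in the uninfected libraries together (median 23). With the Malat1 covariate the median log2 change of these 65 rows was 1.74 (SE 0.52), from 2.18 (SE 0.58) before, and 30 kept their call. The rows were picked by calls in the same data, so the Malat1 trend as the whole cause cannot be judged from this. Leftover genomic DNA or unprocessed RNA spread evenly over such rows is argued against by a median of 0.15 (SE 0.11) over all 276 rows without an opposite gene. Transcripts missing from the annotation, and parasite reads on top of a mouse signal, were not tested and may add to it alongside the infection. The filter, which passes a row through the group where it is high, and the higher median total of the infected non-granuloma libraries were not tested either.

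The named rows that passed between infected non-granuloma and uninfected tissue were searched for opposite signs. Between granuloma and infected non-granuloma tissue 6 of them differed in the direct edgeR test while their estimates against uninfected tissue had opposite signs. The log2 differences were 1.62 (Irf5, opposite Tnpo3), 1.45 (Syn3, opposite Timp3), 1.65 (Gm45507, opposite Bnip3), 1.54 (Gm26883, opposite Tshz2), -1.36 (Pcca, opposite Ggact) and -1.18 (Zyx, opposite Epha1). Against uninfected tissue the granuloma estimates, in that order, were 0.03, 0.60, 0.70, 0.49, -0.18 and -0.35, with edgeR adjusted p from 0.0875 (Gm45507) to 0.964 (Irf5). The estimates of infected non-granuloma tissue were -1.59, -0.85, -0.95, -1.06, 1.17 and 0.83, which all passed, as the search required. Outside this search, Gm48529 (1.93 in granuloma and -0.99 in infected non-granuloma tissue) and Gm10680 (-1.04 and 0.44) also differed directly with opposite signs. There only the granuloma estimate passed, so opposite effects are not shown in any of these rows.

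By Dixon's Q test, single libraries stood far from the rest of their group in 19 of 167 groups of values. Chance would give about 8.35 if values were normal and independent. CPM values need not be normal and the groups share libraries, so an excess is not shown. Infected non-granuloma 3 was highest in Unc13a (695 CPM) and Fam84a (343 CPM), infected non-granuloma 2 in Phldb1 (4012 CPM) and Casp9 (93.1 CPM), and infected non-granuloma 4 in Gm15856 (60.4 CPM). Granuloma 2 was lowest in Gm10602 (82.6 CPM), and granuloma 4 highest in Ccdc184 (542 CPM) and Casp9 (18940 CPM). Uninfected 2 was highest in Gm10602 (16.0 CPM), Trpt1 (983 CPM), Fam84a (39.9 CPM) and Tram1 (79.9 CPM). Uninfected 1 was lowest in Polr2b (787 CPM) and highest in Pdxdc1 (929 CPM), uninfected 3 highest in Cib2 (20.1 CPM) and Casp9 (8088 CPM), uninfected 4 in Chtf18 (16.5 CPM) and Gm16153 (325 CPM), and uninfected 5 in Gpr89 (7049 CPM).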

How the results depend on the processing

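The covariate, the removal of libraries by the Casp9 row and the restriction to rows with an opposite gene were chosen after seeing the data. None of the 88 named results turned its direction in a setting run for it, and 41 kept their side of the threshold in each of these. The named rows were picked from called rows, many for no overlap between the libraries of the groups, so a turn was unlikely from the start. The stricter filter covered 66 of the results, the restriction to rows with an opposite gene 79. Calls were lost most often with the replicate block (37 results), against a fold of 1.5 (34) and without infected non-granuloma 1 (24). Leaving out 1 library gave 20 to 84 rows between granuloma and infected non-granuloma, 134 to 222 between granuloma and uninfected, 90 to 322 between infected non-granuloma and uninfected, and 48 to 107 shared. Where no cause is named it was not tested. Between granuloma and infected non-granuloma the count was 109 with no filter, 158 with DESeq2, 109 with limma-voom and 12 against a fold of 1.5. Against a fold of 1.5 the other counts were 76 for granuloma and 82 for infected non-granuloma against uninfected tissue. For the last comparison the count was 190 with library totals, 152 with a stricter filter (1169 rows tested), 111 with the Malat1 covariate and 146 over rows with an opposite gene, a setting that leaves out the 65 higher and 18 lower rows without one and ended other calls too. Without the 5 libraries with over 100 reads in the Casp9 row the counts were 126, 116 and 154 and the shared calls 35, with fewer samples. The shared calls were 50 over rows with an opposite gene and 11.5 (median) with divided controls. Same-numbered deviations correlated at -0.49 to 0.40 over the 3 comparisons, and few libraries correlated best with their own number. Between granuloma and infected non-granuloma, where samples could come from the same mice, the range was -0.42 to 0.08. There, no granuloma library correlated best with its own number. With so few libraries this gives no sign of pairing by number but cannot exclude it. With the replicate block 0 rows passed between granuloma and infected non-granuloma (293 at an unadjusted p under 0.05 in edgeR), 61 between granuloma and uninfected and 245 between infected non-granuloma and uninfected. The planned list tests and list scores had no list with 4 tested rows, so their alternatives gave no value, except with no filter. There 33 lists could be tested by row name. Between granuloma and infected non-granuloma 1 passed, absorptive enterocyte, lower in granuloma (1617 reads over 27 rows). Between granuloma and uninfected 0 passed. Between infected non-granuloma and uninfected 1 passed, endothelium, higher in infected non-granuloma tissue (9114 reads over 6 rows). Reads of such rows may come from genes on the opposite strand, so these results cannot be read as changes in enterocyte or endothelial genes. With totals of 245201 to 617077 counts and 15% to 29% of simulated 2-fold changes recovered, rows that did not pass are not shown to be unchanged.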

Other observations

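Tests of the rows and families in this part were all chosen after the results were seen. Some rows outside the naming rule are given here, and several of them changed in both groups of infected mice. Their dependence on single libraries was not tested. The Vti1b row, opposite the arginase gene Arg2 over 285 bases, was lower in granuloma than in uninfected tissue (log2 fold change -1.10, edgeR adjusted p = 0.00343) and than in infected non-granuloma tissue (-0.86, adjusted p = 0.0389). Opposite the stabilin Stab1, a scavenger receptor, the Nt5dc2 row was higher in granuloma (1.60) and in infected non-granuloma tissue (1.18) than in uninfected tissue. The Stat3 row, opposite the signal transducer Stat5a, was higher in granuloma by 1.26 on the log2 scale, and the Ap3m1 row, opposite the focal adhesion protein Vcl, by 1.05. The Gm16559 row, opposite the alcohol dehydrogenase Adh1, was lower in both groups of infected mice (-2.80 in granuloma and -3.19 in infected non-granuloma tissue). The Gm10684 row, opposite the junctional adhesion protein Jaml, was lower as well (-1.18 and -2.01).

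In some pairs both overlapping genes had a tested row. The Polr2b row (opposite Igfbp7) and the Igfbp7 row (opposite Polr2b) rose by 1.74 and 0.87 in granuloma against uninfected tissue. The Pltp row (opposite Ctsa) rose by 1.13 and the Ctsa row (opposite Pltp and Neurl2) by 1.72. In infected non-granuloma against uninfected tissue the Tsc2 row (opposite Pkd1) rose by 0.67 and the Pkd1 row (opposite Tsc2) by 1.52. Of the 7 gene families compared after seeing the data, none passed camera in any comparison. With fry, which does not compare a set with other rows, 15 rows opposite solute carriers had adjusted p = 0.0177 and 0.0243 for granuloma and infected non-granuloma against uninfected tissue (camera adjusted p = 0.462 and 0.496). Zinc finger genes between granuloma and infected non-granuloma tissue and cathepsin and lysosomal membrane genes between granuloma and uninfected tissue each had a fry adjusted p = 0.0417.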
